A study of Gallus gallus with 6 samples.

How the data were processed

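Total RNA from the ovaries of 6 hens was labelled with biotin and hybridised to 1-colour Affymetrix chicken arrays, 1 array per hen, per the labels. The deposited table holds a linear signal intensity for each of 38535 probe sets, made by the authors with the Affymetrix software GCOS per the submitters' processing notes; its version and its settings are not given in the sources used here. The values themselves show that each array had been scaled, since the mean after trimming 2% at each end was 500.1 on every array. The 75th percentiles lay between 515 and 541, so no further normalization between arrays was applied. No 2 arrays held identical columns. Scaling to a common mean hides any change in the total amount of messenger RNA, and the signal of dim probe sets is mostly background.

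Group and replicate names follow the labels, which give the disease state of each hen. A prefix in some of the titles (LB) has no stated meaning and was tried as a block. No array batch or date is given in the sources used here, and the groups share no replicate numbers.

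The test, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Probe sets were kept when the mean signal over the 6 arrays was at or above the 40th percentile (66.9), which left 23063 probe sets and removed 15376; 96 Affymetrix control probe sets were left out as well. Signals were transformed as log2(signal + 16) and compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A log2 difference is on that shifted scale and understates the change of dim genes. The SE is limma's moderated SE.

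A background limit was set for each array at the 95th percentile of 59 control probe sets for transcripts that had not been added, a choice made after the values were seen. It lay between 25.5 and 44.6. A gene whose 3 normal arrays all lay at or below their limits has a fold given as "at least", from the mean log2 signal in cancer over the mean log2 of the limits; 17 of the 54 higher probe sets were of this kind.

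Gene names came from the platform's annotation, updated through gene IDs with a RefSeq gene table of the assembly GRCg7b, which was used for names only. 27178 probe sets had 1 gene symbol, 177 had several and 11180 had none in the table; 26863 had a gene ID in the RefSeq table, 315 kept the platform's symbol and 0 symbols changed. A gene was represented by its tested probe set with the highest mean signal (10671 genes), and values given for a gene, folds given as "at least" included, are those of that probe set. The text names up to 12 genes per direction by size of the log2 difference among those past the threshold with no overlap between the groups, filled up by the smallest p where fewer passed. It adds up to 4 members of each list and PAX2, MSX2, FOXA2, EN1, OVAL, CDH1, STAR, CYP11A1, ESR1, PGR and MKI67. Symbols starting with LOC were counted and not named. Other genes in the text were chosen after their values were seen, among them TF, LYZ, AvBD12 and AVD.

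23 gene lists (egg white, shell gland, Mullerian transcription factors, epithelium, motile cilia, follicle steroid genes, oocyte and germ cells, smooth muscle, fibroblast matrix, surface and mesothelium, T cells, B and plasma cells, macrophages, endothelium, red cells, proliferation, interferon, hypoxia and glycolysis, ovarian carcinoma in women, hormone receptors, Wnt signalling, intestine and liver) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, for lists of at least 5 tested genes. Synonyms were matched through the gene table.

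On simulated arrays drawn from the normal means and the fitted spread of the cancer against normal comparison (10 runs over 23063 probe sets, 200 changed in each), the limma step recovered 26.6% of changes of 1 on the log2 scale, 88.8% of changes of 2, 99.8% of changes of 4 and 100% of changes of 6, and 7.24% of its calls were false. The simulation has independent probe sets, so it does not test camera's preset correlation. It used a fitted spread shared by both groups, whereas the median SD of a probe set was 0.344 (log2) among tumours and 0.218 among normal ovaries. Recovery was not split into increases and decreases, and a dim gene cannot fall by the larger sizes on the shifted scale. The recovery and false-call rates therefore describe the simulated arrays and may differ for the real comparison.

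Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, scaling to the 75th percentile, eBayes without a trend or with robust fitting, array weights, the title prefix as a block, the LB hens alone, leaving out each hen, the mean over a gene's probe sets, and a threshold of 0.1. Probe sets without a gene symbol entered the tests and were counted, not named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.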

Results

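Ovarian tissue from 6 hens (Gallus gallus) was profiled on Affymetrix chicken expression arrays, which read the level of each transcript as the brightness of a set of short probes. 3 hens had ovarian tumours (replicates 4, LB14 and LB11) and 3 had ovaries without signs of cancer (replicates 36, LB3 and LB22). The design text states that the groups were alike in age and in laying status, and that the tumours were either confined to the ovary or had seeded the abdomen; the stage of each hen's tumour is not given in the sources used here. The labels name separate hens, so the spread below is between animals. The number of arrays, 3 per group, limits the precision of every value. The comparison asks which transcripts differed between ovaries with tumours and normal ovaries, and the study is known for singling out genes of the oviduct on these samples.

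Ovaries with tumours carried high levels of transcripts for egg-white proteins, which the oviduct normally makes. OVAL, the gene of ovalbumin, the main egg-white protein, was at or below the background limit in all 3 normal ovaries on its only tested probe set, and at least 386-fold higher in cancer (log2 difference 8.53, SE 0.78, n = 3 hens per group, limma adjusted p = 0.00263). The junction gene CDH1 and the transcription factors PAX2, FOXA2 and MSX2 were also higher in all 3 tumours than in any normal ovary. In the other direction, ZP3, which encodes a protein of the egg's coat, fell by 3.52 on the log2 scale (SE 0.38, limma adjusted p = 0.00706). Of 23063 probe sets tested with limma, 54 were higher in cancer (40 gene symbols) and 10 were lower (7 gene symbols) at an adjusted p under 0.05. None of these 64 had overlapping values between the groups, which their selection by p on the same arrays largely fixes in advance. Of all tested probe sets, 15.5% were free of overlap, where chance gives 10%.

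**Figure D1:**
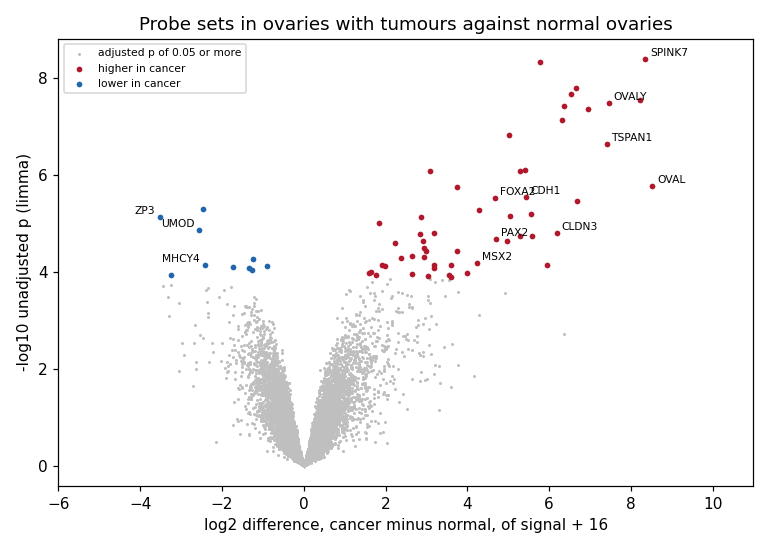
Each point is a probe set, with the log2 difference of signal + 16 (cancer minus normal, 3 hens each) on the x axis and −log10 of the unadjusted limma p on the y axis. Red points are the 54 probe sets higher in cancer and blue points the 10 lower at an adjusted p under 0.05; the differences reach 8.53 for OVAL and −3.52 for ZP3.

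Among genes past the threshold, egg-white genes were 6 of the 12 with the largest increases. All 20 tested members of the egg-white list had a positive difference, 9 were past the threshold among all probe sets and 13 when adjusted over the list alone. Members with a normal mean under the filter limit of 66.9, such as OVAL (26.2) and ORM1 (5.96), were tested only through their tumour signals. Their positive sign was favoured by the filter, so the count of 20 is no test of direction. BPIFB2 and OVOB, below the filter, were not tested. Because OVAL was among the genes the study singled out on these samples, this list is not independent evidence of its direction; without OVAL, 8 of 19 members were past the threshold. SPINK7, the gene of the protease inhibitor ovomucoid, was at least 282-fold higher on the probe set that represents it (log2 difference 8.35, SE 0.38, limma adjusted p = 5.54e-05); its 4 tested probe sets had differences from 2.26 to 8.35, with 3 past the threshold, and on 2 of them normal ovaries were not all at or below background. OVALY, a relative of ovalbumin, was higher by 7.46 (SE 0.43), the small defence peptide gene OvoDA1 by 6.53 (SE 0.36), and SLURP1, listed also as HEP21, by 5.94 (SE 0.86), though SLURP1 lost its call in 8 of 18 alternatives. AvBD11, another defence peptide gene, was at least 87.2-fold higher (log2 difference 6.36, SE 0.37). TF, the gene of ovotransferrin, was already present in normal ovaries at a mean signal of 813 ± 372 (SD, n = 3) and reached 24833 ± 3053 (SD, n = 3) in cancer, although 1 of its 4 tested probe sets had a difference of −0.14. LYZ, lysozyme, rose by 4.96 (SE 0.62; 2.80 on its other probe set, not past the threshold) and AvBD12 by 4.28 (SE 0.45). Not every egg-white gene took part: AVD, which encodes avidin, differed by 0.27 (SE 1.06, adjusted p = 0.964). The list was higher in cancer by limma's camera test with a preset correlation of 0.01 (adjusted p = 2e-27), and past the threshold no longer when the correlation was estimated (adjusted p = 0.0749). With fry it was past the threshold (adjusted p = 0.00297).

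Genes of epithelial identity formed the next group. Of 30 tested members, 27 had a positive difference, 4 were past the threshold and 13 when adjusted over the list alone. CLDN3, a tight junction protein, was at least 49.4-fold higher in cancer (log2 difference 6.20, SE 0.74, limma adjusted p = 0.0127). CLDN10, another claudin, rose by 5.29 (SE 0.44), the keratin KRT40, matched through its synonym KRT20, by 5.57 (SE 0.60), and CDH1, E-cadherin, by 5.44 (SE 0.53). CDH1 had a mean signal of 9987 ± 6527 (SD, n = 3) in cancer against 177 ± 47.1 (SD, n = 3) in normal ovaries. The camera adjusted p was 2.33e-12 with the preset correlation and 0.0749 with an estimated correlation. The tumour of hen LB11 had the lowest of the 3 tumour signals for CLDN3, CLDN10, KRT40 and CDH1.

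Among transcription factors and signals of the Mullerian duct, the embryonic origin of the oviduct, 3 of 18 tested genes rose, and 6 were past the threshold when adjusted over the list alone. PAX2 (normal mean 5.76), EN1 (12.6), FOXA2 (30.6) and MSX2 (60.1) passed the filter only through their tumour signals, which favoured a positive sign. PAX2 was at least 13.7-fold higher on the probe set that represents it (log2 difference 4.71, SE 0.58, limma adjusted p = 0.0146) and differed by 3.54 on its other, which was above background in 1 normal ovary; FOXA2 was higher by 4.68 (SE 0.45, adjusted p = 0.00382) and MSX2 by 4.24 (SE 0.60, adjusted p = 0.0342). MSX2 lost its call in 8 of 18 alternatives, PAX2 in 6 and FOXA2 in 1. EN1, at or below background in all 3 normal ovaries, was at least 6.42-fold higher (log2 difference 3.42, SE 0.87) and not past the threshold (limma adjusted p = 0.223). In tumour LB11 the EN1 signal of 44.5 was also just below that array's background limit of 44.6. DLX5 was not past the threshold either, at 2.65 (SE 0.51, limma adjusted p = 0.106), and its other tested probe set had a difference of −0.45. PAX2, FOXA2, MSX2 and EN1 were chosen by the study on these samples, so the list is not independent evidence of its direction. With the study's genes left out, 0 of 14 members were past the limma threshold, 1 was when adjusted over the list alone, and the camera p was 0.2 (0.245 with an estimated correlation). The full list had a camera adjusted p of 0.000583, and of 0.0822 with an estimated correlation.

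Outside these lists, the largest increases among genes past the threshold were in TSPAN1, a tetraspanin of the cell surface, at least 101-fold (log2 difference 7.41, SE 0.53, limma adjusted p = 0.000492), and RASL10A, a small GTPase related to Ras, at least 65.8-fold on the probe set that represents it (log2 difference 6.94, SE 0.41, adjusted p = 0.000126). On its other probe set, above background in 2 normal ovaries, RASL10A differed by 5.04. RBP, the gene of the riboflavin-binding protein of egg white and yolk, rose by 5.57 (SE 0.68, adjusted p = 0.0134).

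**Figure D2:**
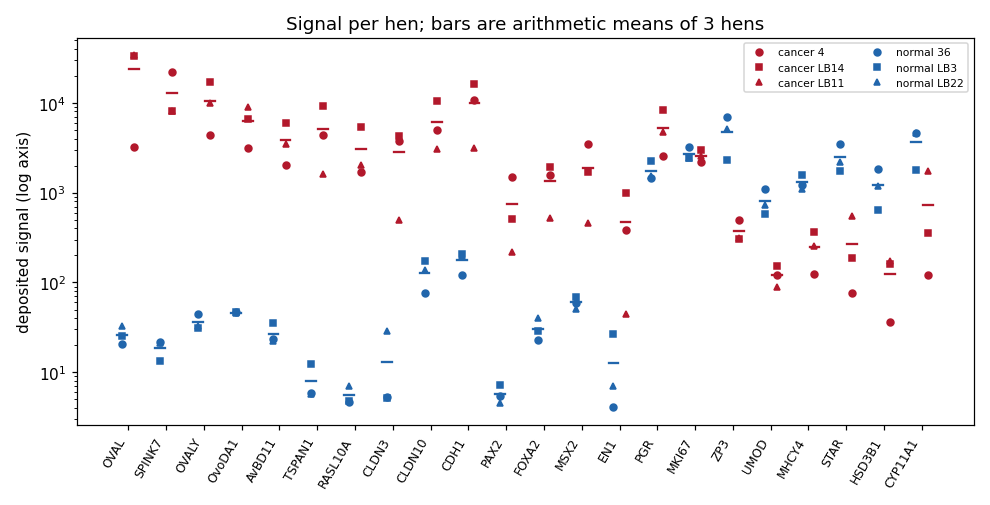
Deposited signal of 22 genes on a log axis, with red symbols for the 3 hens with tumours and blue symbols for the 3 normal hens; short bars are the arithmetic means of each group. OVAL lies between 3251 and 33628 in the tumours and between 20.4 and 33.0 in normal ovaries, whereas MKI67 overlaps between the groups.

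The genes that fell were fewer and changed less. After ZP3, UMOD, listed also as the egg coat gene ZPD, fell by 2.56 (SE 0.30, limma adjusted p = 0.0117). Both stand in the oocyte and germ cell list, in which 2 of 22 tested genes fell and 20 did not pass; in birds, ZP3 and ZPD are made by the granulosa cells around the oocyte. That list had a median difference of 0.10, a mean of −0.16 and an upward camera direction (adjusted p = 0.756; 0.931 with an estimated correlation), so these differ in sign. MHCY4, of the major histocompatibility complex Y region, fell by 2.42 (SE 0.35) and GPR149, an orphan receptor, by 1.73 (SE 0.25). The motor protein gene MYO10 fell by 1.33 (SE 0.20) and the semaphorin receptor gene PLXNC1 by 1.27 (SE 0.19). Limma adjusted p-values of these genes ran from 0.0345 to 0.0386. MYO10 was past the threshold on 1 of 4 tested probe sets (−1.33 to −0.88) and PLXNC1 on 1 of 2 (−1.27 and −1.19). These calls are fragile: GPR149, MYO10 and PLXNC1 each lost theirs in 9 of 18 alternatives and MHCY4 in 6, and without normal hen LB22 no probe set was lower past the threshold. After HSD3B1 and STAR, given below, MME, SLC30A2, GRP and ITGA2 came next by p and were not past the threshold, with differences of −1.78, −2.34, −3.31 and −1.23.

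Genes of the steroid-making follicle cells had negative differences in 20 of 22 tested members. 0 were past the threshold among all probe sets, and 13 were lower when adjusted over the list alone. HSD3B1, which makes progesterone from pregnenolone, differed by −3.25 (SE 0.53, limma adjusted p = 0.0616), STAR, which brings cholesterol into mitochondria, by −3.44 (SE 0.57, adjusted p = 0.0636), CYP17A1 by −3.29 (SE 0.66, adjusted p = 0.125) and CYP11A1, the side-chain cleavage enzyme, by −2.92 (SE 0.80, adjusted p = 0.245). INHBB, an inhibin subunit gene, differed by −3.06 (SE 0.57, adjusted p = 0.0952). The camera adjusted p was 3.65e-11 with the preset correlation and 0.0749 with an estimated correlation. At an unadjusted p under 0.05, limma gave 1167 probe sets higher and 1156 lower over all genes, against 1153 expected by chance in both directions together.

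Cell cycle genes were not higher in the tumours. Of 44 tested members 40 had a negative difference, 0 were past the threshold and 3 were lower when adjusted over the list alone, namely DTL (−1.14), E2F1 (−1.05) and MCM2. MKI67, a marker of dividing cells, differed by −0.04 (SE 0.20, limma adjusted p = 0.968). The camera adjusted p was 2.12e-08 with the preset correlation and 0.349 with an estimated correlation. Fibroblast and matrix genes had negative differences in 20 of 26 members with 0 past the threshold and 0 when adjusted over the list alone, led by VCAN (−1.69, SE 0.44, adjusted p = 0.233). Their camera adjusted p of 0.00114 became 0.736 with an estimated correlation and 0.712 without the tumour of hen 4, whose list mean lay 1.31 below the normal mean on the log2 scale.

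Hormone receptor genes had a positive difference in 10 of 12 tested members, with 0 past the threshold and 0 when adjusted over the list alone. PGR, the progesterone receptor, differed by 1.43 (SE 0.38, limma adjusted p = 0.236) and ESR1, an oestrogen receptor, by 0.61 (SE 0.31, adjusted p = 0.566). In the list for the shell gland, the part of the oviduct where the shell forms, 7 of 9 members were positive, 0 were past the threshold and 2 when adjusted over the list alone; these were BPIFB3 (at least 10.9-fold, log2 difference 3.77, SE 0.65, adjusted p = 0.074) and COL10A1 (at least 3.56-fold, log2 difference 2.93, SE 0.78, adjusted p = 0.235), both at or below background in all 3 normal ovaries on the probe set that represents them. Camera gave adjusted p-values of 0.00384 for the receptors and 0.00194 for the shell gland, each 0.106 with an estimated correlation.

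The other 14 lists were not past camera's threshold with either correlation, although liver (adjusted p = 0.0526) and Wnt signalling (0.0528) lay close to it with the preset correlation and were past it in 8 alternatives each. They include motile cilia (mean difference 0.29), smooth muscle (0.13), endothelium (−0.11), red cells (−0.18), T cells (0.03), B and plasma cells (−0.09), macrophages (−0.16), ovarian surface and mesothelium (0.14), the interferon response (0.13), hypoxia and glycolysis (−0.10), Wnt signalling (0.34), intestine (0.09), liver (0.67) and genes tied to ovarian carcinoma in women (0.39). Adjusted over the list alone, motile cilia had 1 member past the threshold (CAPSL, 2.30), Wnt signalling had 1 higher and 1 lower, liver had 2 (F2 and FETUB) and the carcinoma list had 1, which was CLDN3. In T cells and in the surface list the mean and camera's direction were positive while the median was negative (−0.11 and −0.16). In B and plasma cells the median was 0.03 while the mean and the direction were negative. Smooth muscle stood apart between tumours, at 0.98 above the normal mean in hen LB11 and −0.67 in hen 4.

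**Figure D3:**
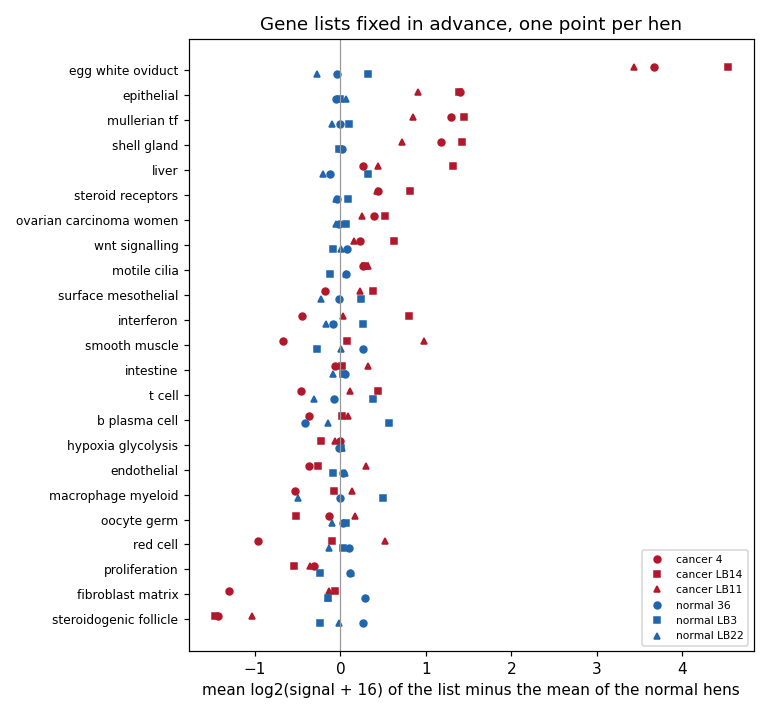
Mean log2(signal + 16) over the tested genes of each of the 23 lists, minus the mean of the 3 normal hens, with red symbols for hens with tumours and blue for normal hens. The egg-white list lies between 3.43 and 4.53 in the tumours, and the follicle list between −1.47 and −1.03.

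Tumours resembled each other less than normal ovaries did. The mean Pearson correlation over tested probe sets, across genes that are not independent, was 0.967 among the normal arrays, 0.925 among the tumours and 0.925 between the groups. The median SD of a probe set was 0.344 (log2) among tumours and 0.218 among normal ovaries. RNA quality, taken as the 3'/5' signal ratio of the actin and GAPDH controls, differed by 0.03 on the log2 scale (cancer 0.14 ± 0.07, normal 0.11 ± 0.11, SD, n = 3 each; exact two-sided permutation test, p = 0.8, where 0.1 is the smallest p that 3 against 3 can give).

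Leaving out 1 hen moved the limma counts to between 23 and 163 higher and between 0 and 25 lower; within the LB hens they were 21 and 1, and with the title prefix as a block 57 and 13. The preset correlation of camera called 8 of the 23 lists here, and between 3 and 12 in other splits of the same 6 arrays.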

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

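Restricting lists to current symbols and dropping genes past the threshold on their own were chosen after seeing the data, as were the splits of the arrays. The 54 higher probe sets became 35 with eBayes without a trend, 21 in the LB hens alone, 87 at an adjusted p under 0.10 and between 23 and 163 when 1 hen was left out. The 10 lower became 6 without the filter, 3 without a trend, 21 with array weights, 1 in the LB hens alone, 24 at an adjusted p under 0.10 and between 0 and 25 when 1 hen was left out. Higher and lower counts were 28 and 3 without normal hen 36, 23 and 5 without LB3, and 24 and 0 without LB22. They were 51 and 25 without tumour 4, 42 and 9 without LB14, and 163 and 19 without LB11. With LB22 left out, 707 higher and 633 lower probe sets had an unadjusted limma p under 0.05. Chance gives 1153 in both directions together. Fewer hens leave fewer degrees of freedom; the cause of the rise without LB11 was not tested. Of the 54, between 22 and 52 were shared when 1 hen was left out, and of the 10, between 0 and 8. Other alternatives stayed within 1.5 times of both counts. With the title prefix as a block, 57 and 13 were called, of which 50 and 6 were shared.

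None of the 22 named genes past the threshold changed sign in the 18 alternatives. 8 were past the threshold in each of them (OVAL, SPINK7, OVALY, TSPAN1, RASL10A, OvoDA1, AvBD11 and CLDN10), whereas 12 lost the call in the LB hens alone and 10 without each of the normal hens 36, LB3 and LB22. GPR149, MYO10 and PLXNC1 lost it in 9 alternatives each, MSX2 and SLURP1 in 8, PAX2 and MHCY4 in 6, CLDN3, RBP and UMOD in 3, KRT40 in 2, and CDH1, FOXA2 and ZP3 in 1. Of 85 named genes not past it, 17 passed in at least 1 alternative.

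Liver and Wnt signalling, not called, were past camera's threshold in 8 of 21 and 8 of 22 alternatives, and 6 other lists in 1 or 2. The 8 list calls became 0 with an estimated correlation and 6 with fry. Those 6 were egg white and Mullerian (fry adjusted p = 0.00297 each), epithelium (0.00917), follicle (0.0125), and shell gland and receptors (0.0281 each). The cell cycle (0.157) and fibroblast (0.638) lists were not past it with fry. Unlike camera, fry does not compare a list with the other genes. Without the genes the study chose on these samples, the Mullerian list had an unadjusted fry p of 0.205. The fibroblast list reversed to a camera adjusted p of 0.504 upward in the LB hens alone, and the Mullerian list had 0.144 without its genes past the threshold. The 3'/5' ratio difference was 0.10 for actin and −0.04 for GAPDH. Signal over background limits the dim genes: with no filter 38439 probe sets were tested.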

Other observations

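The genes in this paragraph were chosen after their values were seen. KCNN2, a calcium-activated potassium channel, was higher in cancer by 2.87 (limma adjusted p = 0.00706), KCNJ16, an inward rectifier, was at least 8.67-fold higher (adjusted p = 0.0424), and SLC9A2, a sodium and proton exchanger, at least 6.20-fold on the probe set that represents it (adjusted p = 0.00263; a log2 difference of 1.92 on the other, not past the threshold). The calcium pump gene ATP2A3 was higher by 2.99 (adjusted p = 0.0225), with 1 of its 3 tested probe sets past the threshold. Both probe sets of CA8, a relative of carbonic anhydrase, were higher (2.85 and 2.94), as were SULF1, a sulfatase of heparan sulfate (2.91; 1.95 on its other probe set, not past the threshold), and the transcription factor SOX7 (1.84, adjusted p = 0.00896). VSNL1, a neuronal calcium sensor, differed by −2.47 (adjusted p = 0.00596) on 1 probe set and by −2.37 (adjusted p = 0.0943) on the other.

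Of the 11 egg-white genes not past the threshold, 4 were higher in all 3 tumours than in any normal ovary. 3 of the 11, chosen after their values were seen, differed widely between tumours. AvBD10 had signals of 7294, 8391 and 70.3 in tumours 4, LB14 and LB11, against 2.0 to 8.3 in normal ovaries, all below background (at least 40.7-fold higher, log2 difference 6.37, SE 1.47, adjusted p = 0.182). ORM1 was at 508 in tumour 4 and at 5.0 and 4.8 in LB14 and LB11. OVOA, listed also as MUC5B, was at 47.9, 243 and 759 in the same order.

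All tests of explanations here, and their bounds, were chosen after the result was seen, and some were revised after a first run. The 9 egg-white genes past the threshold were higher in all 3 tumours, which their selection by p largely fixes in advance. Noise of dim probe sets is argued against as the whole cause of the list's rise, because the mean difference over all 20 tested members was 3.88 and stayed at 3.36 (95% interval over hens 2.39 to 4.33) at pseudocount 64, which shrinks dim differences, with an SD among normal hens of 0.24. The camera adjusted p was then 1.68e-26, but with the preset correlation, which also called lists in other splits of the arrays. At pseudocount 16 the list was not past camera's threshold with an estimated correlation (0.0749). This is the fourth version of the test. The first counted the genes past the threshold that stayed so at pseudocount 64 (8 of 9), the second took the lowest tumour signal among those 9 (1681, highest background limit 44.6), and the third counted tested genes with all 3 tumour signals over 4 times that limit (15 of 20). The first and the second argued against noise on genes picked for their difference, the third left it open, and the fourth takes its bound of 2 SD from the scaling tests below. That bound is weak here, since members dim in normal ovaries entered the test only through their tumour signals. Pseudocount 64 also shrinks the SD among normal hens (0.30 at pseudocount 16, 0.24 at 64). The argument thus rests on the size of the difference, and noise in single dim members stays open. Oviduct tissue in the samples, with its ciliated cells, stays open: the motile cilia list differed by 0.29, with a camera adjusted p of 0.342 with an estimated correlation. Its mean was higher in each tumour (0.27, 0.29 and 0.33 in hens 4, LB14 and LB11) than in any normal hen (−0.13 to 0.06). Of its 21 tested members 12 had a positive and 9 a negative difference. Many cilia genes, DNAH5 and HYDIN among them, were below the filter, and FOXJ1 was not matched. Cells of the tumour that make egg white themselves could give the same egg-white values, and no oviduct array was analysed here.

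Of the follicle steroid genes 20 of 22 had negative differences, with 0 past the threshold and an adjusted p of 0.0749 for the list with an estimated correlation. Array scaling is argued against, because their mean difference was −1.33 after quantile normalization and −1.33 after scaling to the 75th percentile, with an SD among normal hens of 0.26 and 0.27. A smaller share of follicle tissue stays open. The test took 6 lists (smooth muscle, fibroblast matrix, endothelium, red cells, macrophages and T cells). Of these 2 (smooth muscle and T cells) had a mean difference above 0, and none of the 6 was past the threshold with an estimated correlation. This cannot decide the question, since tumour cells in place of follicle tissue need not raise these lists. Epithelium, higher by a mean of 1.23, was not among the 6. A lower expression per follicle cell may give the same values for the follicle genes and was not tested.

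Of the cell cycle genes 40 of 44 had negative differences, with 0 past the threshold and an adjusted p of 0.349 for the list with an estimated correlation. Rescaling the arrays left the mean difference about as large, at −0.40 before, −0.40 after quantile normalization and −0.42 after scaling to the 75th percentile. The SD among normal hens was 0.20 and 0.23 after the rescalings. The bound of 2 SD was thus met after the former and missed after the latter. That bound left array scaling open, but it was also missed before rescaling (−0.404, SD 0.205), so missing it does not bear on scaling. The bound at first used quantile normalization alone, which argued against scaling for this list; asking for both was a later change. Intervals over hens, computed after that, ran from −0.79 to −0.02 and from −0.82 to −0.02. The list means of the groups did not overlap after either rescaling. These values, weighed after the bounds were set, argue against array scaling as the whole cause of the difference. No biological explanation was tested.

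The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. As many probe sets in 1 direction as the 54 higher, and as the 10 lower, came from 1 of the 10 splits each, the real split; the highest of the others was 1. For the list calls, 5 of the 10 splits gave at least the 8 lists of the real split, and the highest other gave 12.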
